A study of Oryza sativa Japonica Group with 29 samples.

How the data were processed

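Gene expression was measured by RNA sequencing in 11 root libraries of rice (Oryza sativa Japonica Group), 3 WT normal, 2 OE normal, 3 WT drought and 3 OE drought. Another 18 samples of the series, measured by ATAC-seq, were not analysed here. The submitters' processing notes name fastp, FastQC 0.11.8, STAR 1.5.2 (version as printed there), SAMtools 1.9, StringTie 1.3.6 and DESeq2, and also Bowtie2 2.2.6, Picard 2.60, MACS2 2.1.0 and DiffBind, with no role given for any. The genome build, the annotation and the strandedness of counting are not given in the sources used here. Without strand, reads of a gene and an overlapping or antisense partner cannot be told apart, and how reads of near-identical copies were split is not known. Values of the RAB16 cluster on chromosome 11 (RAB16B, RAB16C, RAB21), NAS1 and NAS2, ADH1 and ADH2, CAB1R and CAB2R, the small heat shock proteins and the PIP aquaporins are therefore uncertain between copies.

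Each library has a table of 55986 loci with coordinates. TPM values deposited by the authors sum to 1000000 in each library and were the measure tested. FPKM values deposited by the authors, a constant multiple of TPM within a library, were used as an alternative. Coverage deposited by the authors was used only for its ratio to FPKM, which gives an implied depth in gigabases per library. Read counts were not used here, so no count model was fitted and no counting interval can be given. An exact 0 can be a failed estimate, and a gene at 0 is described as listed at 0.

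Genes with at least 1 TPM in at least 2 libraries were tested, 23699 in all, on log2(TPM + 1). One group-means model over the 11 libraries was fitted with limma 3.58.1 in R 4.3.3, moderated with a mean-variance trend (7 residual and 2.92 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The contrasts were OE against WT in normal conditions, OE against WT after drought, drought against normal in WT, drought against normal in OE, and the interaction, which is the OE drought response minus the WT drought response. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for joining and plots. The model, contrasts, lists of gene groups, rule for named genes and alternatives were fixed before the data were examined, with the exceptions given here.

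The tables name loci by identifier and hold no symbols or product names. The planned matching of lists through product names was void because the reference table has none. Loci were instead written from knowledge of the gene families after the identifier type and the TPM of 5 loci had been seen and before any test. A name was accepted when the reference table (assembly ASM3414082v1) held that symbol or synonym on the same chromosome within 5 Mb and with a length ratio of 0.9 to 1.1. Of 319 loci written, 199 were accepted, 55 of them with equal length, while 71 had no symbol in the table, 47 were refused and 2 were not among the loci listed. The same aliases set against 39800 random loci were accepted in 2.161% of draws. Names therefore rest on symbol, chromosome, position and length. The lists of ABA-responsive bZIP factors and VP1, potassium and sodium transporters, root development regulators and other stress-induced genes were added at that stage. Lists without accepted members are not reported. All 6 ABA receptor loci written were refused or had no symbol in the table, so the list planned as ABA receptors and SnRK2 kinases holds only kinases.

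The rule for named genes took, per contrast, the target and partner genes, the 10 largest rises and 10 largest falls among called genes with an accepted name, at least 5 TPM in the higher group and no overlap between groups (no overlap rule for the interaction), and up to 4 members per list by lowest adjusted p. Unnamed loci are given by identifier, at most 2 per direction and comparison, and loci outside the rule are said to be chosen after their values were seen. The text gives values for only part of the genes that the rule takes, and 1 gene is not reported here, though it stays in the counts of its list. Lists with at least 3 tested members, 28 in all, were tested with limma camera at a preset correlation of 0.01, adjusted over lists. No list passed in any contrast with an estimated correlation. At the preset correlation, splits that mixed WT normal and WT drought libraries also passed up to 9 lists.

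The fits were tested on simulated data of 23699 genes with the measured spread per group and 100 genes changed at each of log2 1 and 2. For OE against WT in normal conditions, the fit over 11 libraries recovered 53% and 81% with 4 false calls among 23499 unchanged genes, and the fit on the 5 libraries compared recovered 88% and 96% with 40. For OE against WT after drought, the fit over 11 libraries recovered 59% and 92% with 311 false calls, and the fit on the 6 libraries compared recovered 13% and 62% with 13. The shared spread is therefore too wide for the normal comparison and too narrow for the drought comparison. The planned fit was kept as the reported one, and a fit with 1 weight per group was added after seeing the data. It recovered 98% and 100% with 160 false calls in normal conditions, and 40% and 83% with 49 false calls after drought.

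The other settings run were a pseudocount of 0.1, no filter, a filter of 5 TPM, FPKM, median-ratio scaling, quantile normalization, no variance trend, library quality weights, only the libraries compared, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. Where leaving out a library left OE normal with 1 library, that library was assumed to vary like the other groups.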

Results

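RNA was measured by sequencing in roots of 25-day-old rice seedlings grown in hydroponic culture. Wild type plants of the cultivar ZH11 (WT) were compared with plants over-expressing OsNMCP1 (OE), a lamin-like protein of the nuclear periphery. Roots were taken in normal conditions or after 3 h without water supply. The libraries fell into 4 groups, with 3 WT normal, 2 OE normal, 3 WT drought and 3 OE drought libraries. For all 6 drought libraries the labels give genomic DNA as molecule and source, while their titles name RNA sequencing, and they were taken as RNA from the titles. Their values correlated with those of the normal libraries at 0.6864 to 0.8627. The series calls the replicates biological without saying whether they came from separate cultures, so p-values measure the spread between these samples. The deposited values gave an implied depth of 8.56 to 9.29 gigabases for WT normal, 5.79 to 7.34 for OE normal, 8.23 to 11.95 for WT drought and 7.0 to 7.14 for OE drought. Between 20110 and 21812 loci per library reached 1 TPM. Replicates correlated across genes at 0.9949 to 0.9963 in WT normal and 0.995 in OE normal, against 0.9274 to 0.9816 in WT drought and 0.9609 to 0.9758 in OE drought. WT drought replicate 3 stood apart from its group, at 0.9274 and 0.9439 with WT drought replicates 1 and 2, against 0.9282, 0.9211 and 0.929 with the OE drought libraries. On the second principal component, which held 11.7% of the variance, it stood at 17.2, against 83 and 74.4 for the other WT drought libraries and -53.9 to -32.2 for OE drought. The median SD of log2(TPM + 1) was 0.074 and 0.075 in the WT and OE normal groups and 0.27 and 0.253 in the WT and OE drought groups. All fold changes below are differences of mean log2(TPM + 1), which understate the change of weakly expressed genes, and all adjusted p-values are from limma with Benjamini-Hochberg adjustment over 23699 genes unless a gene list is named.

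The over-expressed gene was examined first, as a check on the genotype labels. OsNMCP1 (LOC_Os01g56140, chromosome 1, 32327698 to 32332777, build not given in the sources used here) stood at 35.5, 37.6 and 36.3 TPM in the WT normal libraries and at 184 and 167 TPM in the OE normal libraries. It stood at 37.4, 28.1 and 46.4 TPM in the WT drought libraries and at 452, 424 and 347 TPM in the OE drought libraries. Its level was higher in OE by 2.23 on the log2 scale in normal conditions (SE 0.19, adjusted p = 0.000332) and by 3.44 after drought (SE 0.17, adjusted p = 2.74e-06). In WT the drought difference was 0.00 (SE 0.17, adjusted p = 0.99), and in OE the transcript rose by 1.2 (SE 0.19, adjusted p = 0.000364). NMCP1A (LOC_Os02g48010), the other rice gene of this family examined, differed by -0.02 (adjusted p = 1) in normal conditions and -0.12 (adjusted p = 0.54) after drought. SWI3C1 (LOC_Os11g08080), a subunit of a chromatin remodeling complex, differed between OE and WT by 0.16 (adjusted p = 0.746) in normal conditions and -0.24 (adjusted p = 0.072) after drought.

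**Figure D1:**
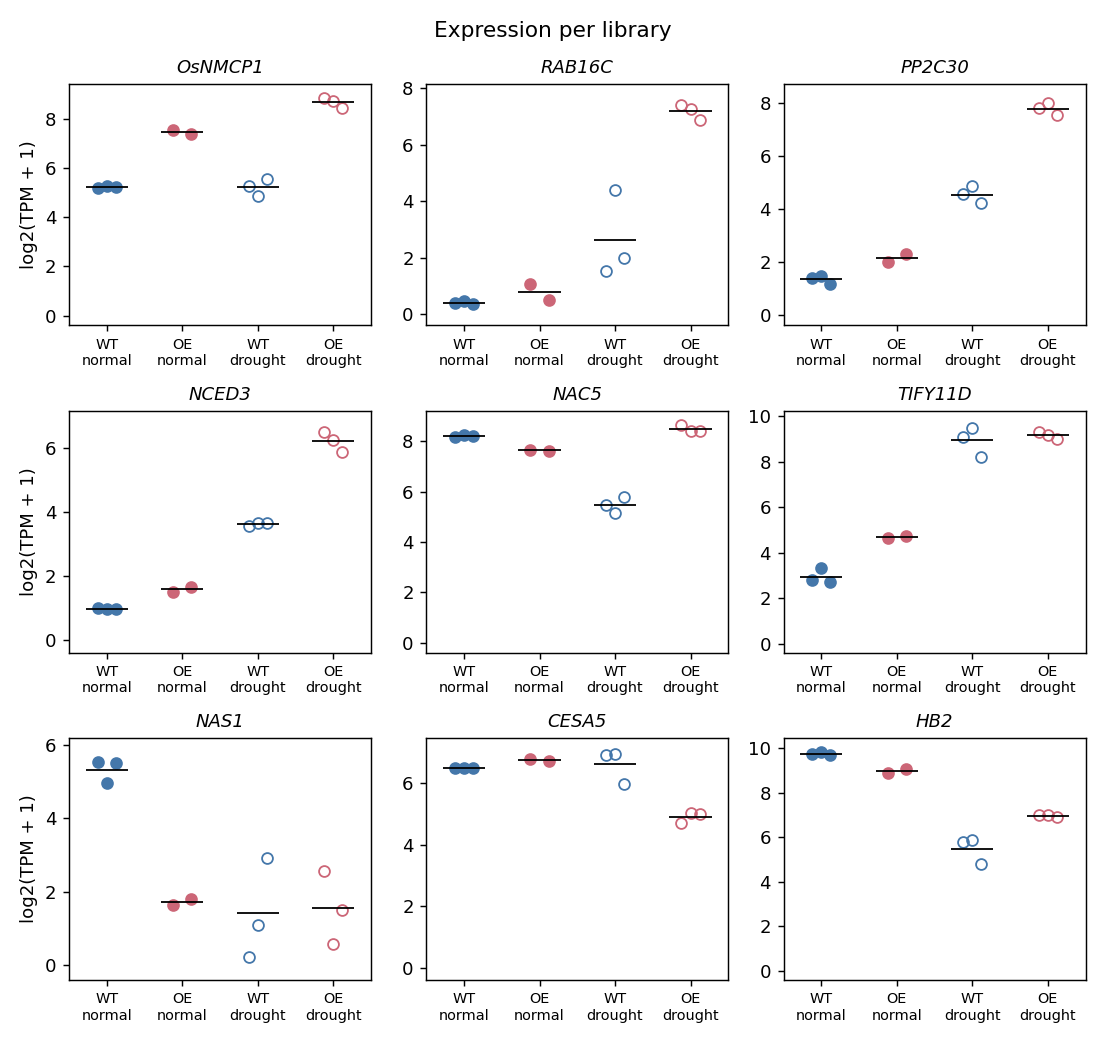
Expression of 9 genes as log2(TPM + 1) in each of the 11 libraries, grouped by genotype and condition. Points are libraries and lines are group means, and OsNMCP1 was higher in OE by 2.23 in normal conditions and 3.44 after drought.

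The comparison of OE with WT in normal conditions addressed what OsNMCP1 over-expression does in watered roots. Of 8 iron and zinc uptake genes, 3 were lower in OE and 5 did not pass. NAAT1, an aminotransferase of phytosiderophore synthesis, fell by 2.81 (SE 0.29, adjusted p = 0.00113, n = 3 and 2), from 7.36 ± 2.001 to 0.170 ± 0.185 TPM (mean ± SD). YSL2, a metal-nicotianamine transporter, fell by 3.09 (SE 0.36, adjusted p = 0.00242), and NAS1, a nicotianamine synthase, fell by 3.61 (SE 0.72, adjusted p = 0.0376). The jasmonate repressor gene TIFY11D rose by 1.74 (SE 0.32, adjusted p = 0.0275), the phosphate transporter gene PT1 by 1.44 (SE 0.27, adjusted p = 0.0293) and the protein phosphatase gene PP2C68 by 1.14 (SE 0.23, adjusted p = 0.0391). The small heat shock protein gene HSP18.1 fell by 1.29 (SE 0.27, adjusted p = 0.0446).

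Among the fixed lists, 3 of 8 iron and zinc uptake genes fell, with 4 lower when adjusted over the list alone (limma camera, adjusted p = 3.64e-05, and adjusted p = 0.235 with an estimated correlation). Under median-ratio scaling 2 fell, and on the 5 normal libraries alone 4 fell and 1 rose. Of 10 jasmonate synthesis and JAZ genes, 1 rose and 9 did not pass, with 6 higher when adjusted over the list alone (camera adjusted p = 2.58e-05, and adjusted p = 0.248 with an estimated correlation). TIFY11A, TIFY11B and TIFY10C differed by 2.11 (adjusted p = 0.166), 1.66 (adjusted p = 0.185) and 0.87 (adjusted p = 0.151). Of 6 heat shock proteins, 1 fell, with 2 lower when adjusted over the list alone (camera adjusted p = 0.00386, and adjusted p = 0.248 with an estimated correlation). None of 5 low oxygen genes passed, with 2 lower when adjusted over the list alone (camera adjusted p = 0.00421, and adjusted p = 0.248 with an estimated correlation), and the hemoglobin gene HB2 differed by -0.78 (adjusted p = 0.245). The lists of DREB and CBF factors, phenylpropanoid and lignin synthesis, and target and partner genes also passed as higher, at camera adjusted p = 0.0497, 0.0251 and 0.0341, each with adjusted p = 0.248 with an estimated correlation. When adjusted over the list alone, 1 member of each of these 3 lists was higher, and in the target list that member was OsNMCP1 itself.

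Shoot tissue markers moved with these groups. None of 3 photosynthesis genes passed over all genes and 3 were lower when adjusted over the list alone (camera adjusted p = 0.00341, and adjusted p = 0.248 with an estimated correlation). Mean levels went from 444 to 153 TPM for CAB1R, from 453 to 157 TPM for CAB2R and from 102 to 20.1 TPM for RBCS, in the same libraries in which the iron and zinc, heat shock and low oxygen lists were lower and the jasmonate list was higher.

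In all, 417 genes were called between OE and WT in normal conditions, 294 of them higher (70.5%), and 287 of them changed at least 2-fold. Of the 8 named genes called, only OsNMCP1 and NAAT1 were called in each of the 11 fits that left out 1 library. Without OE normal replicate 1 or 2, 39 or 35 genes were called, and without WT normal replicate 1, 2 or 3, 129, 187 or 127 were called, while 1300 were called without WT drought replicate 3. The calls of YSL2, TIFY11D, PT1, PP2C68, NAS1 and HSP18.1 were lost without OE normal replicate 1 or 2, and the highest adjusted p was 0.0861, 0.302, 0.315, 0.356, 0.351 and 0.375. Those of NAS1, PT1 and PP2C68 were also lost without any of the WT normal libraries, those of TIFY11D and HSP18.1 without WT normal replicate 1 or 3, and the drought libraries also decided NAS1 (WT replicate 2, OE replicate 3), PP2C68 (OE replicate 2) and HSP18.1 (WT replicates 1 and 2, OE replicates 2 and 3). Drought libraries enter these calls only through the shared spread, not through the fold change. Over the 11 fits the fold change ranged from -3.243 to -2.983 for YSL2, 1.615 to 1.935 for TIFY11D and 1.382 to 1.501 for PT1. It ranged from 1.113 to 1.187 for PP2C68, -3.793 to -3.507 for NAS1 and -1.588 to -1.118 for HSP18.1. Median-ratio scaling called 216 genes and ended the calls of TIFY11D (adjusted p = 0.0725), PT1 (0.0759), PP2C68 (0.0797), NAS1 (0.0724) and HSP18.1 (0.0938). Fitted on the 5 normal libraries alone, whose spread is smaller, 7102 genes were called, among them 9 of the 10 jasmonate genes (TIFY11A adjusted p = 0.00297) and all 3 photosynthesis genes. In that fit 4 of 5 low oxygen genes and 4 of 6 heat shock protein genes were lower. There 3 of 4 DREB and CBF genes and 3 of 5 phenylpropanoid and lignin genes were higher.

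The comparison of OE with WT after drought addressed the same question in stressed roots. Of 7 clade A protein phosphatase genes and 8 LEA and dehydrin genes, 6 each were higher in OE. RAB16C, a dehydrin, rose by 4.56 (SE 0.59, adjusted p = 0.000493, n = 3 and 3), from 8.28 ± 10.2 to 147 ± 26.9 TPM. The clade A genes PP2C30 and PP2C68, whose products restrain abscisic acid (ABA) signaling, rose by 3.24 (SE 0.19, adjusted p = 6.24e-06) and 3.17 (SE 0.21, adjusted p = 1.01e-05). NCED3, an enzyme of ABA synthesis, rose by 2.58 (SE 0.16, adjusted p = 7.95e-06), and BZIP23, an ABA-responsive transcription factor gene, by 1.11 (SE 0.18, adjusted p = 0.0015), from 113 to 240 TPM. The cellulose synthase gene CESA5 fell by 1.71 (SE 0.23, adjusted p = 0.000613).

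Of 7 clade A phosphatase genes, 6 rose over all genes and when adjusted over the list alone (camera adjusted p = 1.15e-06, and adjusted p = 0.134 with an estimated correlation). Of 8 LEA and dehydrin genes, 6 rose, with 7 when adjusted over the list alone (camera adjusted p = 3.45e-06, and adjusted p = 0.224 with an estimated correlation), among them RAB16B by 3.29, LEA3 by 3.61 and EMP1 by 2.72. LEA3 stood at 2.655 without WT drought replicate 1 and 4.733 without WT drought replicate 2, and RAB16B at 4.184 without WT drought replicate 2. EMP1 was weakly expressed, at 7.374, 6.861 and 8.048 TPM in OE drought and at most 0.4502 TPM in any other library. In ABA synthesis and breakdown 3 of 5 genes rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0218, and adjusted p = 0.219 with an estimated correlation). The catabolic genes ABA8OX2 and ABA8OX3 rose by 1.77 and 1.97, and ABA8OX1 fell by 2.25. All 5 low oxygen genes were higher in OE than in WT, also when adjusted over the list alone (camera adjusted p = 0.000169, and adjusted p = 0.134 with an estimated correlation). The alcohol dehydrogenase genes ADH1 and ADH2 were higher by 1.52 and 2.201 and HB2 by 1.49. Of 11 heat shock factors, 3 rose, with 2 when adjusted over the list alone (camera adjusted p = 0.0121, and adjusted p = 0.224 with an estimated correlation), HSFC2A by 2.96 and HSFC2B by 2.98 among them. Single genes outside these lists included the transcription factor gene NAC5, which rose by 3.02 (SE 0.16, adjusted p = 2.86e-06), and the auxin response gene IAA9, which rose by 2.84 (SE 0.26, adjusted p = 7.5e-05).

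All 8 cellulose synthase genes fell, also when adjusted over the list alone (camera adjusted p = 0.00613, and adjusted p = 0.521 with an estimated correlation), and 6 fell under median-ratio scaling. Lignin genes fell in 4 of 5 cases, also when adjusted over the list alone (camera adjusted p = 0.0424, and adjusted p = 0.377 with an estimated correlation), and 2 fell under median-ratio scaling. CAD2, a member of that list, fell by 1.06. Diterpenoid phytoalexin genes fell in 6 of 8 cases, also when adjusted over the list alone (camera adjusted p = 0.0424, and adjusted p = 0.466 with an estimated correlation), with CYP99A3 down from 32.7 to 3.28 TPM and CPS4 from 49.1 to 16.5 TPM. The aquaporin gene PIP1-3 fell by 2.33, the ammonium transporter gene AMT1-3 by 3.66, and the cold-response factor gene DREB1A by 2.49. Of 3 photosynthesis genes, 2 fell, also when adjusted over the list alone (camera adjusted p = 0.352), CAB2R by 2.86 (adjusted p = 0.00333) and CAB1R by 1.33 (adjusted p = 0.0275).

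Between OE and WT after drought, 9144 genes were called, with 2861 higher and 6283 lower (31.3% higher). The median of all genes was -0.20, and with median-ratio scaling, which removes that shift, 8595 genes were called, with 4406 higher and 4189 lower (51.3% higher). Because the drought libraries spread more than the normal ones, a fit sharing 1 spread over all 11 libraries calls too many genes here. On simulated data of 23699 genes it called 311 of 23499 unchanged genes, against 13 with the 6 drought libraries alone. With those 6 libraries 3464 genes were called, 1242 higher and 2222 lower. The list counts were then 5 of 7 higher for clade A phosphatases, 5 of 8 for LEA genes, 2 of 5 for ABA synthesis and breakdown (with 0 lower), 3 of 5 for low oxygen and 2 of 11 for heat shock factors, and 5 of 8 lower for cellulose synthases, 2 of 5 for lignin, 5 of 8 for diterpenoids and 1 of 3 for photosynthesis. In that fit ABA8OX1 (adjusted p = 0.0819), ABA8OX3 (0.0514) and CAB1R (0.103) did not pass. The call of ABA8OX1 was lost without WT or OE drought replicate 2 (adjusted p up to 0.0571), and that of CAB1R without WT drought replicate 1 or 2 or OE drought replicate 3 (adjusted p up to 0.0941). Without WT drought replicate 3, 11625 genes were called and 5 rather than 8 lists passed. Of the 38 named genes called, 8 moved by over 1.5 times when 1 library was left out. Besides LEA3 and RAB16B these were RAB16C (3.998 to 5.434, without WT drought replicates 1 and 2), ABA8OX1 (-3.147 to -1.525), AMT1-3 (-4.626 to -3.099), HKT8 (-3.778 to -2.249) and HSFC2A (2.51 to 3.628), each without WT drought replicates 1 or 3, and CAB2R (-3.561 to -2.184, without OE drought replicates 1 and 3).

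The drought response of WT addressed how roots of the parent cultivar react to 3 h without water. By median, jasmonate genes rose most among the 28 lists. TIFY11A rose by 6.71 (SE 0.57, adjusted p = 8.56e-06, n = 3 and 3), from 1.87 to 383 TPM, and TIFY11D by 5.996 (SE 0.29, adjusted p = 3.12e-07), from 6.83 to 522 TPM. AOS2, an enzyme of jasmonate synthesis, rose by 5.69 (SE 0.33, adjusted p = 7.72e-07). The hemoglobin gene HB2 fell by 4.26 (SE 0.24, adjusted p = 6.99e-07), from 860 to 46.2 TPM, and the small heat shock protein gene HSP18.0 by 4.13 (SE 0.29, adjusted p = 2.67e-06).

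All 10 jasmonate genes rose, also when adjusted over the list alone (camera adjusted p = 1.74e-09, and adjusted p = 0.178 with an estimated correlation). Diterpenoid phytoalexin genes rose in 7 of 8 cases, also when adjusted over the list alone (camera adjusted p = 1.3e-05, and adjusted p = 0.178 with an estimated correlation), with CPS4 up by 4.65 and CYP99A3 by 2.77. All 3 WRKY factors rose, also when adjusted over the list alone (camera adjusted p = 0.00821, and adjusted p = 0.275 with an estimated correlation), WRKY71 by 5.69 and WRKY24 by 4.83. Clade A phosphatase genes rose in 4 of 7 cases, also when adjusted over the list alone (camera adjusted p = 0.00618, and adjusted p = 0.279 with an estimated correlation), PP2C30 by 3.19 and PP2C49 by 3.03. Of 8 LEA genes, 5 rose, also when adjusted over the list alone (camera adjusted p = 0.0101, and adjusted p = 0.494 with an estimated correlation), with LIP9 up by 3.34. Single genes that rose included NAC4 by 5.56, DREB1C by 6.61, the cytokinin oxidase gene CKX5 by 4.94, and the aquaporin genes TIP1-2 by 3.16, PIP1-3 by 2.31 and PIP2-3 by 2.17. BZIP23 rose by 0.86 (SE 0.18, adjusted p = 0.00208). NAS1 fell by 3.91, NAC5 by 2.76, YSL2 by 2.33, and the aquaporin gene PIP2-6 by 2.08. Of 3 photosynthesis genes 2 passed, as RBCS fell by 4.66 and CAB1R fell by 1.53 (camera adjusted p = 0.57).

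Without WT drought replicate 3, TIFY11A stood at 7.555, DREB1C at 7.9, RBCS at -5.331 and NAS1 at -4.669, and without WT drought replicate 1 DREB1C stood at 5.923, RBCS at -3.907 and NAS1 at -3.318. In WT, 15244 genes were called, with 4813 higher and 10431 lower (31.6% higher). The median of all genes was -0.35, and with median-ratio scaling 13395 were called, with 6809 higher and 6586 lower (50.8% higher). Under that scaling SWI3C1 turned from -0.02 (adjusted p = 0.859) to 0.36 (adjusted p = 0.00934), and NMCP1A, which fell by 0.58 (adjusted p = 0.00534), stood at -0.20 (adjusted p = 0.288). Sequencing batch is not given in the labels. The normal and the drought libraries stand in separate blocks of the series. A batch between these blocks, which was not tested, cannot be told apart from drought in either genotype.

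The drought response of OE addressed the same treatment in over-expressing roots. The sources used here do not say whether the OE normal and OE drought plants were the same line. By median, LEA and dehydrin genes rose most among the 28 lists. RAB16C rose by 6.41 (SE 0.66, adjusted p = 2.39e-05, n = 3 and 2), from 0.746 to 147 TPM, RAB21 by 5.59 (SE 0.93, adjusted p = 0.000447, and 6.245 without OE drought replicate 3) and LEA3 by 5.45 (SE 0.90, adjusted p = 0.000414). PP2C30 rose by 5.64 (SE 0.22, adjusted p = 9.66e-08), from 3.43 to 220 TPM, and NCED3 by 4.63 (SE 0.18, adjusted p = 1.09e-07). The cellulose synthase genes CESA4, CESA7 and CESA9, which act in secondary walls, fell by 3.002, 3.04 and 3.16.

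All 10 jasmonate genes rose, also when adjusted over the list alone (camera adjusted p = 7.35e-08, and adjusted p = 0.186 with an estimated correlation), TIFY11E by 5.24 and AOS2 by 5.03. All 8 LEA genes rose, also when adjusted over the list alone (camera adjusted p = 2.62e-06, and adjusted p = 0.189 with an estimated correlation). Clade A phosphatase genes rose in 6 of 7 cases, also when adjusted over the list alone (camera adjusted p = 1.02e-05, and adjusted p = 0.186 with an estimated correlation). Diterpenoid genes rose in 5 of 8 cases, also when adjusted over the list alone (camera adjusted p = 0.00447, and adjusted p = 0.252 with an estimated correlation), with CPS4 up by 2.77. All 3 WRKY factors rose, also when adjusted over the list alone (camera adjusted p = 0.00869, and adjusted p = 0.189 with an estimated correlation). ABA synthesis and breakdown genes rose in 3 of 5 cases, also when adjusted over the list alone (camera adjusted p = 0.0153, and adjusted p = 0.186 with an estimated correlation). Cellulose synthase genes fell in 7 of 8 cases, also when adjusted over the list alone (camera adjusted p = 0.0498, and adjusted p = 0.796 with an estimated correlation). BZIP23 rose by 1.94 (SE 0.20, adjusted p = 2.34e-05). AMT1-3 fell by 4.65, HSP18.0 by 4.23, NAS3 by 3.51, the sodium transporter gene HKT1 by 2.92 and the root patterning gene SHR1 by 2.88. The silicon channel gene NIP2-1 fell by 3.205. All 3 photosynthesis genes fell, also when adjusted over the list alone (camera adjusted p = 0.575), and none did under median-ratio scaling.

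In OE, 16772 genes were called, with 4607 higher and 12165 lower (27.5% higher). The median of all genes was -0.56, and with median-ratio scaling 14913 were called, with 7583 higher and 7330 lower (50.8% higher). Under that scaling SWI3C1 turned from a fall of -0.42 (adjusted p = 0.00599, and 0.06 without OE normal replicate 1) to 0.22 (adjusted p = 0.0998), and NMCP1A, which fell by 0.68, stood at -0.03 (adjusted p = 0.87).

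**Figure D2:**
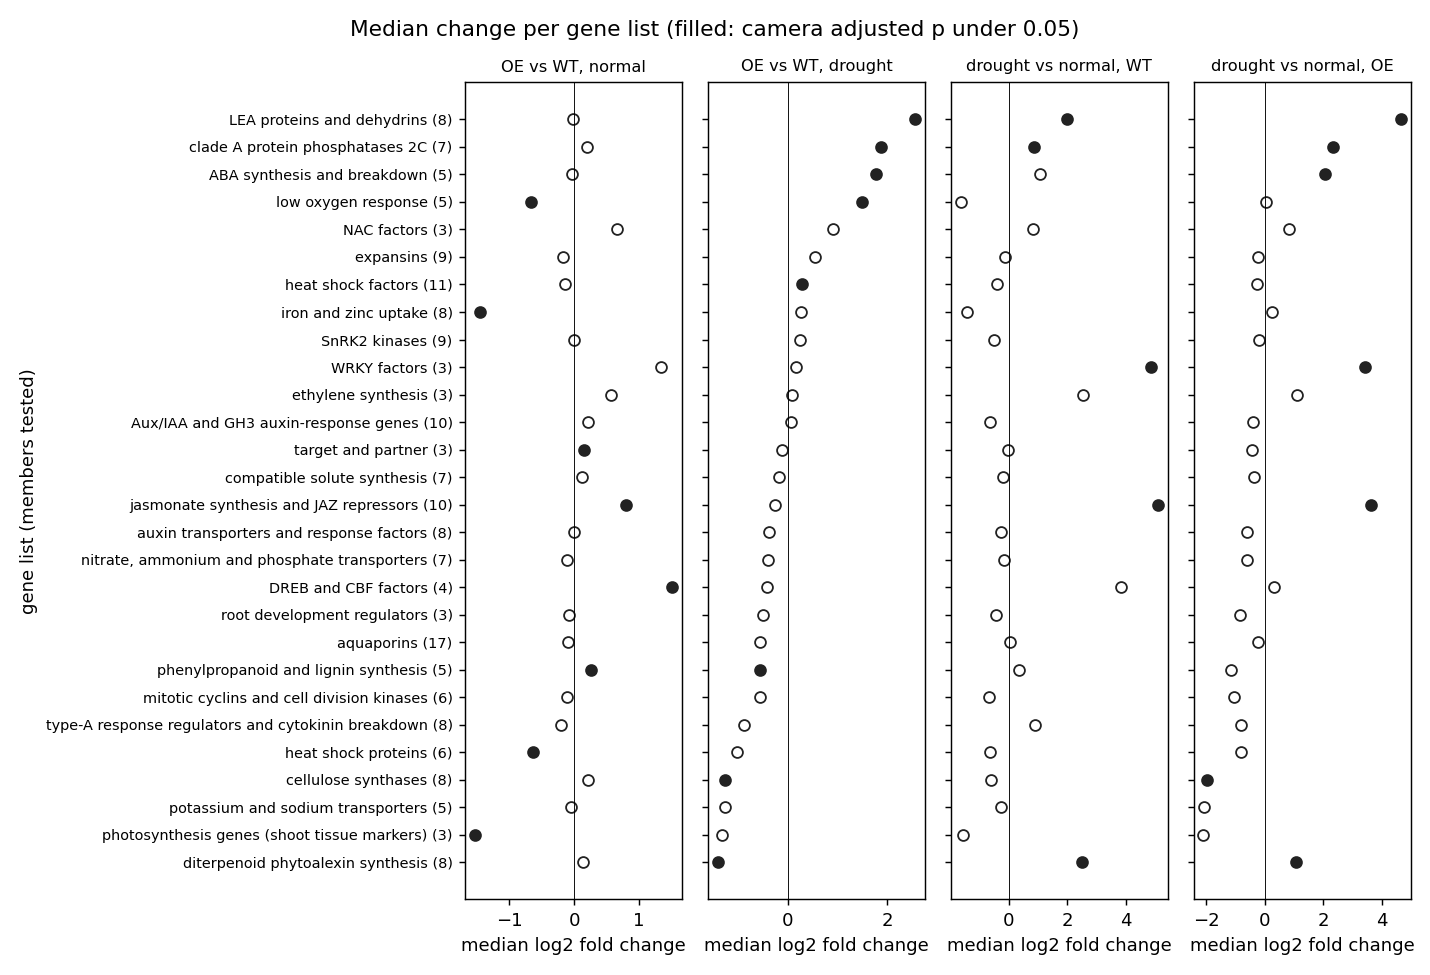
Median log2 fold change of each fixed gene list in 4 comparisons, with the number of tested members in parentheses. Filled points passed the camera test at an adjusted p under 0.05 with the preset correlation, 8, 8, 5 and 7 lists from left to right, and none passed with an estimated correlation.

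The interaction addressed whether the drought response differed between genotypes, as a test of the difference itself. A line difference between the OE normal and OE drought plants, which the sources used here do not exclude, would also enter this term. Clade A phosphatase genes had a positive interaction in 5 of 7 cases and LEA genes in 4 of 8, and SnRK2 kinase genes in 1 of 9 (camera adjusted p = 0.121). RAB16C had an interaction of 4.18 (SE 0.89, adjusted p = 0.0136), PP2C49 of 2.49 (SE 0.41, adjusted p = 0.00484), NCED3 of 1.98 (SE 0.24, adjusted p = 0.00107) and BZIP23 of 1.08 (SE 0.27, adjusted p = 0.0249). The calls of RAB16C and BZIP23 were lost without an OE normal library (adjusted p up to 0.0725 and 0.103). NAC5 fell in WT and rose by 0.84 in OE, an interaction of 3.598 (SE 0.23, adjusted p = 3.06e-05). DREB1A, which rose by 4.01 in WT and differed by 0.19 (adjusted p = 0.615) in OE, had an interaction of -3.82 (SE 0.44, adjusted p = 0.000814).

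When adjusted over the list alone, 5 of 7 clade A phosphatase genes had a positive interaction (camera adjusted p = 1.8e-06, and adjusted p = 0.131 with an estimated correlation). LEA genes did in 4 of 8, with 6 when adjusted over the list alone (camera adjusted p = 1.88e-06, and adjusted p = 0.196 with an estimated correlation), with EMP1 at 2.94. Low oxygen genes did in 4 of 5, with 5 when adjusted over the list alone (camera adjusted p = 1.93e-06, and adjusted p = 0.103 with an estimated correlation), and ADH1, which fell by 0.49 in WT and rose by 1.77 in OE, had 2.26. After drought all 5 low oxygen genes fell in WT, while in OE 2 rose and 2 fell, with a median of 0.04. The median difference of the low oxygen list between OE and WT was -0.665 in normal conditions and 1.485 after drought. Part of its interaction is therefore a normal difference. ABA synthesis and breakdown genes had a positive interaction in 2 of 5, with 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00979, and adjusted p = 0.155 with an estimated correlation). Heat shock factors did in 2 of 11, also when adjusted over the list alone (camera adjusted p = 0.00979, and adjusted p = 0.196 with an estimated correlation). Iron and zinc uptake genes were positive in 4 of 8 and negative in 2, with 5 and 2 when adjusted over the list alone (camera adjusted p = 0.0115, and adjusted p = 0.229 with an estimated correlation), with YSL2 at 3.58. Of these 8, 3 were already lower in OE in normal conditions, and 6 fell in WT after drought. Their interaction holds that normal difference. Cellulose synthase genes were negative in 4 of 8, with 8 when adjusted over the list alone (camera adjusted p = 0.00328, and adjusted p = 0.437 with an estimated correlation), with CESA5 at -1.96. Lignin genes were negative in 3 of 5, with 4 when adjusted over the list alone (camera adjusted p = 0.00498, and adjusted p = 0.196 with an estimated correlation). Diterpenoid genes were negative in 5 of 8, with 6 when adjusted over the list alone (camera adjusted p = 0.0175, and adjusted p = 0.32 with an estimated correlation), with CYP99A3 at -2.998. Jasmonate genes were negative in 3 of 10, with 5 when adjusted over the list alone (camera adjusted p = 0.0211, and adjusted p = 0.429 with an estimated correlation). The median difference of the jasmonate list between OE and WT was 0.797 in normal conditions and -0.25 after drought. Its interaction therefore also holds a normal difference. Under median-ratio scaling 2 cellulose synthase, 2 lignin, 3 diterpenoid and 0 jasmonate genes were negative, and under quantile normalization 4, 4, 2 and 2.

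The interaction was called for 3778 genes, with 1091 positive and 2687 negative (28.9% positive). The median of all genes was -0.23, and with median-ratio scaling 2683 were called, with 1443 positive and 1240 negative (53.8% positive). Of the 26 named interaction calls, 15 held in each of the 11 fits that left out 1 library. The others were OsNMCP1, BZIP23, RAB16C, NAS1, HSFC2A, RAB16B, HSFC2B, WRKY71, MYB2, NAR2.1 and CPS2, all lost without an OE normal library, with highest adjusted p of 0.0782, 0.103, 0.0725, 0.113, 0.0603, 0.131, 0.078, 0.111, 0.131, 0.131 and 0.0826. Those of BZIP23, NAS1, RAB16B, MYB2 and NAR2.1 were also lost without any of the WT normal libraries, and that of WRKY71 without WT normal replicate 1 or 3. Among drought libraries, WT replicate 2 also decided NAS1, WRKY71, MYB2 and NAR2.1, WT replicate 1 decided RAB16B and NAR2.1, OE replicate 1 decided RAB16B, and OE replicate 2 decided RAB16B and MYB2. The count was 1110 or 1082 without OE normal replicate 1 or 2, 1878, 2100 or 1908 without WT normal replicate 1, 2 or 3, 7436 without WT drought replicate 3 and 5995 without OE drought replicate 3. Without WT drought replicate 1, RAB16C, NAS1 and HSFC2A stood at 3.627, 3.144 and 3.116. Without WT drought replicate 2, RAB16C and RAB16B stood at 5.062 and 4.092, and without WT drought replicate 3, NAS1 and HSFC2A stood at 4.495 and 4.234.

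Across the 23699 genes, which are not independent replicates, the drought responses of WT and OE correlated at a Pearson r of 0.81 and a Spearman rho of 0.807, with a slope of 0.929. Of 12500 genes called in both genotypes, 97.8% had the same sign. The other 276 were called in opposite directions, each with a called interaction, among them NAC5, ADH1, ADH2, YSL2, ARF10, CAD2 and TIP2-1.

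**Figure D3:**
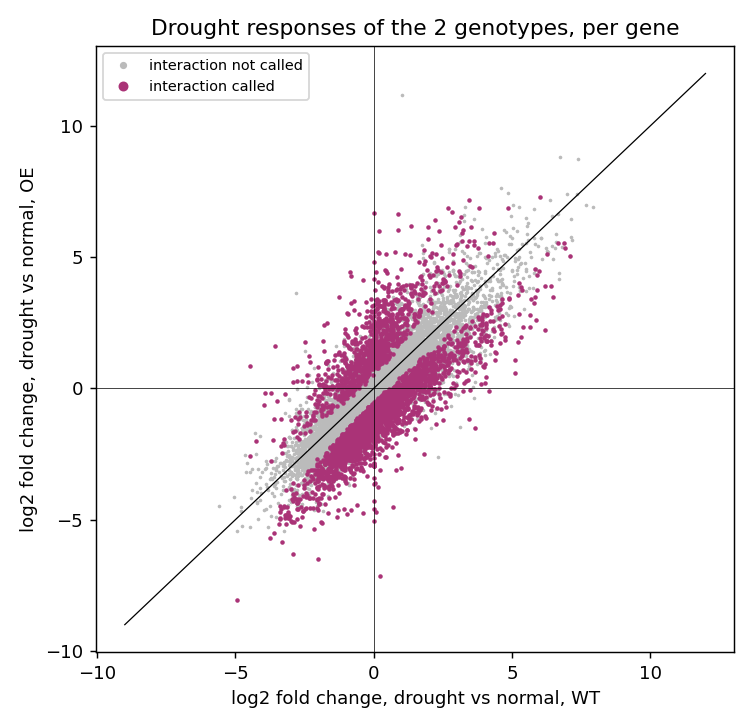
Log2 fold change after drought in WT (x axis) and in OE (y axis) for each of the 23699 genes, with the line of equal response. Purple points are the 3778 genes with a called interaction, and the responses correlated across genes at 0.81.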

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

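Of the tests below, those of shared WT libraries, of shoot tissue and of depth were chosen after the result was seen. The test of a shared response was set before. A test of depth by expression level, also set before, was void, as log2(TPM + 1) shrinks the changes of weakly expressed genes.

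The drought response differed between genotypes by the interaction term for 3778 genes. Positive differences among named genes were 4.18 for RAB16C, 3.74 for NAS1, 3.598 for NAC5, 3.58 for YSL2, 3.56 for HSFC2A, 3.19 for RAB16B, 2.94 for EMP1, 2.57 for IAA9, 2.49 for PP2C49, 2.45 for HSFC2B, 2.26 for both ADH1 and HB2, 2.21 for ADH2, 1.98 for NCED3, 1.2 for OsNMCP1 and 1.08 for BZIP23. For NAS1 and YSL2 the term holds a normal difference, as both were already lower in OE in normal conditions and fell in WT after drought. Negative differences were -3.82 for DREB1A, -2.998 for CYP99A3, -2.32 for ARF10, -2.27 for WRKY71, -1.96 for CESA5, -1.91 for PIP1-3, -1.89 for MYB2, -1.89 for NAR2.1, -1.88 for CPS4 and -1.86 for CPS2. Normal differences also entered the terms of genes other than NAS1 and YSL2. OE minus WT in normal conditions was 1.335 for DREB1A (limma adjusted p = 0.0854), -0.74 for ADH1 (0.0596) and -0.776 for HB2 (0.245). These did not pass in the reported fit but passed on the normal libraries alone. Each had the sign opposite to its interaction and enlarged it. For OsNMCP1 (2.235) and NCED3 (0.603) the normal difference had the sign of the interaction and made it smaller. Under median-ratio scaling WRKY71 (limma adjusted p = 0.0612), MYB2 (0.0833), NAR2.1 (0.0686) and CPS2 (0.0516) did not pass. With a pseudocount of 0.1, NAS1 (0.0789), RAB16B (0.0942) and CPS2 (0.154) did not pass. Of these 26, 11 were lost when an OE normal library was left out, OsNMCP1 (adjusted p up to 0.0782), BZIP23 (0.103), RAB16C (0.0725), NAS1 (0.113), HSFC2A (0.0603), RAB16B (0.131), HSFC2B (0.078), WRKY71 (0.111), MYB2 (0.131), NAR2.1 (0.131) and CPS2 (0.0826).

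A candidate explanation is 1 shared response taken further in OE. Of the 2449 interaction genes also called in the WT response, 49.8% had the sign of that response, which argues against it as the whole cause. Noise in the shared WT libraries pulls this share down. So can the OE normal libraries, whose difference from WT normal already went with the WT drought response (r = 0.499 across genes). The share was not computed under median-ratio scaling, which removes the shift of all genes. The 276 genes called in opposite directions in the 2 genotypes are among these 2449 and lower that share by construction. They are therefore no separate evidence. On the first principal component, which held 75% of the variance, the WT normal libraries stood at -121.5 to -116.4 and OE normal at -97.3 to -95.7. There WT drought stood at 41.7 to 68.8 and OE drought further out, at 103.2 to 136.9. A shared response taken further in OE therefore stays open as part of the cause. Lower depth of the OE drought libraries (7.08 gigabases on average, against 9.47 in WT drought) would widen their spread. The median SD of OE drought minus that of WT drought was -0.017, but both drought groups spread over 2 times as much as the normal ones, which can hide noise from depth, so depth cannot be told apart from the other explanations. Genotype, a difference between OE lines and any batch of the OE drought libraries, none of them tested, stay open.

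Genes called between OE and WT in normal conditions moved as in the WT drought response. Of those higher, 190 were also higher after drought in WT (59.7 for independent lists), and of those lower, 96 were also lower (54.1), and the fold changes correlated across genes at 0.499, against 0.167 in simulated unchanged groups. Both comparisons use the same 3 WT normal libraries, too few to split, so part of the overlap may come from them. The covariance of 0.265 stood above the simulated mean of 0.0062 by 0.259 (highest of 100 simulations 0.00943), which argues against independent noise between replicates alone. The simulation held no offset shared by the 3 WT normal libraries, so such an offset stays open. Less shoot tissue in the OE samples would raise root genes and lower shoot genes. No list of genes of 1 tissue covers enough of the genes called (0 of those higher on the list of root regulators and 0 of those lower on the shoot list), so less shoot tissue cannot be told apart from a root change for either.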

How the results depend on the processing

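The fit with 1 weight per group, and every alternative for the correlation of responses, were chosen after seeing the data. In normal conditions OE against WT gave 417 genes, 216 with median-ratio scaling, 7165 with library quality weights, 7102 with only the groups compared and 6652 with weights per group. After drought it gave 9144, 3464 with only the groups compared, 4933 with weights per group and 10888 with quality weights, and the interaction gave 3778, or 9981 with quality weights. In simulated data for OE against WT, the fits on the groups compared and with weights per group also called more changed genes in normal conditions and fewer after drought. Quality weights and the interaction were not simulated. Lists called with quality weights were 5 for OE against WT after drought and 8 for the WT response. With an estimated correlation 0 lists were called in all 5 contrasts, and fry called 4, 17, 13, 18 and 15. SWI3C1 reversed with median-ratio scaling, to 0.36 in the WT and 0.22 in the OE drought response, as that scaling removes the shift of all genes.

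Leaving out each library in turn gave 35 to 1300 genes for OE against WT in normal conditions (without OE normal replicate 2 and WT drought replicate 3), 6452 to 11625 after drought, 13005 to 16036 for the WT and 13496 to 18194 for the OE response, and 1082 to 7436 for the interaction. OsNMCP1 ranged from 2.17 to 2.31 in normal conditions and 3.25 to 3.603 after drought, the lists called from 6 to 9, 5 to 10, 5 to 7, 6 to 8 and 9 to 11 in the 5 contrasts in turn, and the correlation of responses from 0.754 to 0.832. Over 147 named gene results, leaving out a library ended a call in 85 cases and added a call in 13. Median-ratio scaling ended 14 calls and added 1.

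Replicate numbers did not pair the libraries. Deviations of same-numbered libraries correlated at -0.132 to 0.0594, and 2 of 11 libraries correlated best with their own number. With the replicate block 216, 8429, 14913, 16481 and 2685 genes were called in the 5 contrasts. The block ended 6 named calls and added 0. In normal conditions these were NAS1 (limma adjusted p = 0.0911), PP2C68 (0.0985) and HSP18.1 (0.1). In the interaction they were NAS1 (0.0516), MYB2 (0.0501) and NAR2.1 (0.0587). Depth limits weakly expressed genes, and without counts no counting interval was available.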

Other observations

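The test of sequence carried by OE plants was chosen after the result was seen, and the splits of the samples were set before.

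Other gene groups varied by member. After drought, OE against WT, 8 of 17 aquaporin genes fell and 1 rose (camera adjusted p = 0.0849), 4 of 8 type-A response regulator and cytokinin breakdown genes fell (adjusted p = 0.117), RR10 by 1.94 among them, and 3 of 5 potassium and sodium transporter genes fell and 1 rose (adjusted p = 0.337), with HKT8 at -2.96 (-3.778 without WT drought replicate 3 and -2.249 without WT drought replicate 1). Root development regulators fell in 1 of 3 cases (adjusted p = 0.624). On the 6 drought libraries alone, 5 aquaporin genes fell and 0 rose, and 3 type-A regulator and cytokinin breakdown genes fell. In that fit 3 potassium and sodium transporter genes fell and 0 rose. Under median-ratio scaling 6 aquaporin genes fell and 1 rose, and 3 type-A regulator and cytokinin breakdown genes fell. Both ABA-responsive bZIP genes tested rose, and 1 of 2 other stress-induced genes rose, in lists too short for a set test. In the WT drought response all 5 low oxygen genes fell (adjusted p = 0.0597), and 6 of 8 iron and zinc uptake genes fell (adjusted p = 0.231). Under median-ratio scaling 4 low oxygen genes and 5 iron and zinc uptake genes fell there.

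A set of 10 loci, chosen after their values were seen, stood at 5 TPM or more in both OE normal libraries and under 0.5 TPM in all WT libraries. LOC_Os03g18779 (chromosome 3, 10518910 to 10520197) stood at 171 and 169 TPM in OE normal and at no more than 0.482 TPM in any other library. LOC_Os03g43100 (chromosome 3, 24046089 to 24047243) stood at 40.6 and 40.8 TPM in OE normal, at 4.93, 6.47 and 2.51 TPM in OE drought, and was listed at 0 in WT. By the same limits 15 loci stood at 5 TPM or more in all OE drought libraries and under 0.5 TPM in each other library, such as LOC_Os03g48690 (chromosome 3, 27752287 to 27755346) at 83.1, 100.9 and 123.2 TPM in OE drought and listed at 0 elsewhere. Another of the 15 was EMP1 (LOC_Os05g28210), a member of the LEA list that was higher in OE after drought. On in 1 group alone were thus 9 loci in OE normal and 15 in OE drought, against 0 in WT normal and 0 in WT drought. If sequence carried by all OE plants were the cause, the 10 loci could be expected in OE drought too. Of the 10, 1 (10%) was at 0.5 TPM or more in all 3 OE drought libraries, and 9 were under 0.5 TPM in each. The share of 97.9% among 14382 other genes is not a like measure, as those genes need not be off in WT. For the 9 loci the values argue against carried sequence that stays expressed after drought. LOC_Os03g43100 was on in all OE libraries, though lower in OE drought. Carried sequence stays open for this locus, as expression values alone cannot decide it. Whether the OE normal and OE drought plants were the same line is not given in the sources used here, and a difference between lines or a library batch may remain, as neither was tested.

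The 6 libraries of each 3 against 3 comparison make 10 splits, too few for a share under 0.05. OE against WT after drought called 9144 genes in the real split and at most 305 in another, and 8 lists against at most 7. The WT drought response called 15244 genes against at most 0, and 5 lists against at most 9, with 8 of the 10 splits giving as many lists. Each other split mixes the real groups, so a true difference widens its spread and lowers its gene count. The gene counts of those splits are therefore no measure of calls without a difference. Their list counts show that camera at the preset correlation also passes lists when the groups are mixed.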
